A study of Mus musculus with 4 samples.

How the data were processed

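RNA sequencing was done on total RNA from mouse ES cells grown on embryonic fibroblasts with LIF and from cells kept without LIF for 2 days (1 library) or 5 days (1 library, labelled embryoid body), with 2 ES libraries as controls. The labels name a total RNA library kit and do not say whether it records the strand of a transcript. The values used here are the FPKM that the authors deposited, 1 value per gene and library for 47633 genes. Per the submitters' processing notes, Trimmomatic 0.36, STAR and Cufflinks and the mouse build mm10 were used; their roles, options, order, annotation release and strand setting are not given in the sources used here. FPKM divides by gene length and library total, so a few very abundant transcripts lower all others: the 10 highest genes held 15.5% of the FPKM sum in ES 1, 9.8% in ES 2, 44.7% after LIF withdrawal and 17.4% in the library labelled embryoid body. The FPKM sums were 582093, 528718, 865343 and 594026 in that order. Median-of-ratios factors were 0.997, 1.018, 1.014 and 0.973, and the median log2 change over tested genes was 0.04 for LIF withdrawal and -0.01 for the library labelled embryoid body, so no rescaling was applied in the main test.

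Depth was taken from single-transcript genes of at least 3000 nt. The most common low value of FPKM times exon length was read as a single fragment, in bins of 0.05 on the log2 scale. This implied 31.5, 26.4, 18.1 and 26.4 M fragments, where equal values mean the same bin. A floor of 3 fragments per library was used, and intervals and floors cover counting error only. Gene positions, types and overlaps came from GENCODE mouse release 21 on mm10: 47219 of the 47633 identifiers matched without their version, 414 did not, and 82.1% had the same version. The position checks use this annotation, which need not be the release behind the FPKM.

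Genes at 1 FPKM or more in at least 1 library (15676) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, moderated with a trend on mean expression). All 4 libraries were in 1 model, whose 1 residual degree of freedom comes from the ES pair. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1; such changes understate those of low genes because of the pseudocount of 1. A size rule without a test took genes at least 2-fold from both ES libraries in the same direction. Lists of genes were tested with camera (preset correlation of 0.01) where at least 5 members passed the filter, with Benjamini-Hochberg adjustment over all lists and both comparisons; 29 lists were fixed before the data were examined, holding 558 gene names of which 552 matched. With a correlation estimated from these 4 libraries no list was called. That setting tests on the 1 residual degree of freedom, so it could hardly call any list and cannot decide whether one changed. Feeder genes after LIF withdrawal had an estimated correlation of -0.0281, below the preset 0.01, and were still not called. For the library labelled embryoid body against LIF withdrawal the median difference of each list was set against 10000 random lists. Further work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

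The named genes were fixed by a rule before the data were examined. For each comparison with ES cells it took the 8 largest rises and 8 largest falls among called genes at 5 FPKM or more on the higher side, leaving out predicted gene names and small RNAs. It added up to 4 called members per list, or the 2 most abundant where none was called, and the 3 largest rises and falls of long non-coding genes. The size rule stood in where fewer than 16 genes passed, which was so for the library labelled embryoid body, where 0 passed (limma; 4338 genes were at unadjusted p under 0.05). For the comparison of the derived libraries it took the 5 highest and 5 lowest. The same rule was applied again to the strand-clear set, so those names were added after values were seen. A further result is not reported here.

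The strand-clear set (7175 genes: protein-coding or long non-coding, at least 1000 nt of exons, outside every gene body on the opposite strand) was chosen after several gene sets had been fitted and is an addition to the planned design. The steps were tested on simulated data drawn from the ES pair's residuals, with 200 genes per draw changed in the place of the library labelled embryoid body; changes in the place of LIF withdrawal were not simulated. Over all genes limma recovered 0% of changes of 1.5 and 0% of changes of 3 on the log2 scale, with 0 false calls. For strand-clear genes, it recovered 97.4% and 100%, and the size rule 100% of both. Those changes were placed only in genes at 5 FPKM or more in ES cells, so recovery of lower genes was not tested. The list test called a list raised by 1 on the log2 scale in 20 of 20 draws, and 1 of 1060 other list tests. Smaller changes of a list were not simulated, and the median of each list called in the main test was smaller. Unchanged groups were simulated 50 times against the same ES libraries for the background counts and shared-control values. Antisense genes, overlapping genes, pseudogenes and near-identical family members are uncertain, because how reads were divided among them is not given in the sources used here. This also holds for genes of these kinds that the text does not mark.

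Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no variance trend, no fold threshold, camera on ranks or with an estimated correlation, and each ES library alone. Restrictions of the gene set by strand overlap and length were added after seeing the data. Leaving out an ES library leaves no residual degree of freedom, so the test itself could not be repeated that way.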

Results

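RNA sequencing measured transcript levels in mouse embryonic stem (ES) cells of the 129S2/SvPas strain and in cells derived from them. ES cells are pluripotent cells held undifferentiated by leukaemia inhibitory factor (LIF), a cytokine that signals through STAT3, and these cultures were kept on growth-arrested embryonic fibroblasts. The 4 libraries comprised 2 of ES cells, 1 of cells kept for 2 days without LIF, and 1 labelled embryoid body (an aggregate of differentiating ES cells) after 5 days without LIF. The libraries were made from total RNA, so non-coding transcripts were measured beside mRNA. Values were FPKM. Depth was estimated from the most common low value of FPKM times exon length, read as a single fragment. It was 31.5 M fragments for ES 1, 26.4 for ES 2, 18.1 for LIF withdrawal and 26.4 for the library labelled embryoid body. At these depths, 3 fragments in a gene model of 1 kb corresponded to 0.095, 0.113, 0.166 and 0.113 FPKM, limits that cover counting error only. Genes at 1 FPKM or more numbered 13170 in ES 1, 12793 in ES 2, 14262 after LIF withdrawal and 13407 in the library labelled embryoid body. The labels do not say that the ES libraries came from separate cultures, so the limma p-values of single genes measure only the spread between these samples, which may be technical. The camera p-values at the preset correlation compare the genes of a list with all other genes. They measure spread across genes and not between samples. Neither derived library had a replicate.

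The ES libraries differed by more than counting noise, with a median squared deviation of 1.51 to 6.29 times the Poisson value, and were counted as 2 samples. Over 15676 genes they correlated at r = 0.956, across genes that are not independent replicates, and 684 genes were at least 2-fold apart between them (581 higher in ES 1). Processed pseudogenes made up 469 of these, with 421 higher in ES 1. In 92.1% of those 469 pseudogenes the library labelled embryoid body lay nearer ES 1 than ES 2, against 13.2% for LIF withdrawal. A narrower set was therefore also examined, chosen after the data were seen: protein-coding and long non-coding genes with at least 1000 nt of exons that lie outside the body of every gene on the opposite strand. In this strand-clear set of 7175 genes the ES libraries correlated at r = 0.997 and 15 genes were at least 2-fold apart.

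The check of the labels used pluripotency and mesoderm markers. Pou5f1, the POU transcription factor needed for pluripotency, was at 480.3 ± 11.9 FPKM (SD, n = 2) in ES cells, 455 after LIF withdrawal and 461 in the library labelled embryoid body. Nanog, another core pluripotency factor, was at 110.5 ± 3.79, 103 and 156 FPKM. Klf4, a LIF-responsive factor of the naive state, was at 170.2 ± 7.57, 121 and 131 FPKM. T, the brachyury gene of the primitive streak, was at 1.07 ± 0.0943, 0.558 and 0.127 FPKM. In the library labelled embryoid body T was thus below its ES level (log2 change -0.88, limma adjusted p = 0.139 over all genes and 0.0308 in the strand-clear set) and Nanog above it (0.49, limma adjusted p = 0.139 and 0.0381), with neither reaching the 2-fold threshold. Klf4 was below its ES level (-0.37, limma adjusted p = 0.161 and 0.0535). Pou5f1, Nanog and T thus go against that label as far as differentiation is concerned while Klf4 does not, and the sample is named by its label throughout.

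**Figure D1:**
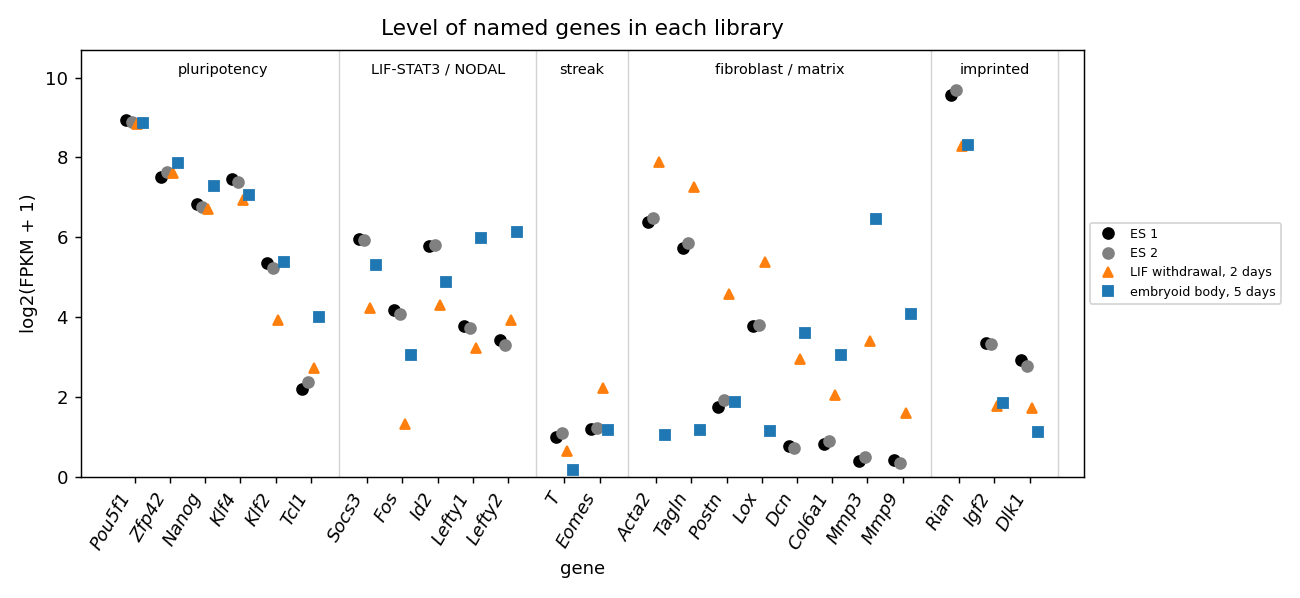
Level of named genes in the 4 libraries, on a log2(FPKM + 1) axis, with 1 point per library (black and grey circles, ES 1 and ES 2; orange triangles, LIF withdrawal; blue squares, the library labelled embryoid body). Fos and Socs3 lay lowest after LIF withdrawal, and Acta2, at 85.7 ± 4.20 FPKM in ES cells, was at 234 after LIF withdrawal and 1.06 in the library labelled embryoid body.

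The first comparison asked how ES cells changed after 2 days without LIF. Fos, a subunit of the AP-1 transcription factor, fell from 16.4 ± 0.902 FPKM (SD, n = 2) to 1.52, a log2 change of -2.79 (SE 0.08, limma adjusted p = 0.0249). Socs3, the feedback inhibitor of LIF receptor signalling, fell from 60.5 ± 1.14 to 17.8 FPKM (-1.71, adjusted p = 0.0134), and Id2, an inhibitor of basic helix-loop-helix factors, from 54.3 ± 0.297 to 18.7 FPKM (-1.49, adjusted p = 0.00953). Igfbp5, a secreted binding protein for insulin-like growth factors, rose from 0.656 ± 0.0579 to 21.9 FPKM (3.79, adjusted p = 0.0135). The matrix metalloproteinase genes Mmp10 and Mmp3, whose products degrade extracellular matrix, rose to 11.8 and 9.50 FPKM from 0.483 ± 0.125 and 0.369 ± 0.0711.

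Further falls by the naming rule were Fosb (-2.33), the Notch ligand Dll1 (-2.06), the growth factor receptor Fgfr2 (-1.76), the imprinted growth factor Igf2 (-1.57), the microtubule protein Map2 (-1.55) and the non-coding Kis2, which went from 17.7 ± 0.46 to 3.65 FPKM (-2.01). Ifitm1, an interferon-induced membrane protein gene, fell from 118 ± 3.64 to 42.1 FPKM (adjusted p = 0.0262). In mm10, Fos (ENSMUSG00000021250.13) lies on chromosome 12, 85473890 to 85477273, plus strand, Socs3 (ENSMUSG00000053113.3) on chromosome 11, 117966079 to 117970047, minus strand, and Igfbp5 (ENSMUSG00000026185.8) on chromosome 1, 72857932 to 72874884, minus strand. Klf2, a transcription factor of the naive state, was at 37.9 ± 2.44 and 14.2 FPKM (log2 change -1.35), with limma adjusted p = 0.0566 over all genes and 0.0166 over the strand-clear set, where it fell. In that set the proliferin genes Prl2c3 and Prl2c2, prolactin-family hormones, also rose, from 0.929 ± 0.457 to 28.7 FPKM and from 0.331 ± 0.40 to 15.5 FPKM (adjusted p = 0.0174 and 0.0204). Their sequences are near-identical, so the division of reads between them is uncertain. Zfp202, a zinc finger gene, rose from 0.457 ± 0.0110 to 11.4 FPKM, and Ypel4 from 0.0809 ± 0.0534 to 7.45 FPKM. Olfr986, an olfactory receptor gene next to Zfp202 on the same strand of chromosome 9, was listed at 0 in both ES libraries and at 13.5 FPKM after LIF withdrawal. Hmgn5 and Phpt1 fell in the strand-clear set, to 2.17 and 5.11 FPKM.

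The 8 largest rises by the naming rule were of another kind, because every such gene lies in or across an expressed gene on the opposite strand. They were CT010467.1, Slc24a5, Cd247, Rpgrip1, Acat3, Apol7d, Prss23os and Fam57a. Slc24a5, a pigment-cell ion exchanger gene, was listed at 0 in both ES libraries and reached 50.6 FPKM, and 39.5% of its exon length is covered by exons of Myef2, which was at 79.96 FPKM in ES cells. Cd247, which encodes a T-cell receptor chain, was likewise at 0 in both and reached 44.3 FPKM opposite Pou2f1. Acat3 went from 0.158 ± 0.0277 to 23.6 FPKM opposite the chaperonin gene Tcp1, at 355 FPKM in ES cells. The labels do not state whether strand was used in counting, so the levels of these genes are uncertain.

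Over all 15676 genes limma called 1203 genes, 1147 higher and 56 lower, and 680 of them were listed at 0 in both ES libraries. Such genes show no spread in the ES pair, so their p-values rest on variance borrowed from other genes. In the strand-clear set limma called 220 genes, 175 higher and 45 lower, and each of the 137 genes of that set that were called over all genes was called there too. Simulated unchanged libraries gave 0 calls over all genes and a mean of 0.58 (highest 4) in the strand-clear set. By size without a test, 1517 genes were at least 2-fold from both ES libraries (1386 higher), against 379 in simulated unchanged libraries, and 198 against 3.44 in the strand-clear set. The 379 came from ES-pair differences drawn with random signs among genes of like level, so they are no matched background for pseudogenes. The spread came from the ES pair alone, with 1 residual degree of freedom, so the lone library was assumed to vary as ES cells did. In simulations, which changed genes only in the place of the library labelled embryoid body, no change was recovered over all genes and 97.4% of changes of 1.5 on the log2 scale in the strand-clear set. The strand-clear changes were placed only in genes at 5 FPKM or more in ES cells, so recovery at lower levels was not tested.

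Among the gene lists fixed beforehand, fibroblast feeder genes rose after LIF withdrawal. Of 22 members tested 8 rose and 0 fell by limma, with 16 at unadjusted p under 0.05, and 11 rose adjusted over the list alone. Postn (periostin) went from 2.59 ± 0.286 to 22.7 FPKM, S100a4 from 13.3 ± 1.08 to 73.2, the proteoglycan gene Dcn from 0.679 ± 0.0224 to 6.68 and the collagen gene Col5a2 from 7.68 ± 0.0584 to 28.4. The list's median log2 change was 0.88 (camera adjusted p = 0.000305, and adjusted p = 0.881 with an estimated correlation). With an estimated correlation the test has 1 degree of freedom, so here and below that value cannot decide whether a list changed. In the strand-clear set 6 of 15 members rose, among them Postn, Dcn and Col5a2. S100a4 was not among them, so its rise is less certain. The imprinted list fell as a set (median -0.33, camera adjusted p = 0.000518, and adjusted p = 0.881 with an estimated correlation). Of its 22 members Igf2 fell and Rtl1 rose, with 4 falls and 1 rise adjusted over the list alone, and Rtl1 overlaps genes on the opposite strand. In the strand-clear set Rian, a maternally expressed non-coding transcript, fell from 788 ± 47.1 to 311 FPKM, and Dlk1, a paternally expressed gene of the same cluster, from 6.27 ± 0.509 to 2.31 FPKM. The LIF-STAT3 target list also fell (median -0.24, adjusted p = 0.0347, and adjusted p = 0.881 with an estimated correlation), a call lost under 5 other settings too. Of its 16 members Fos and Socs3 fell and Ier3, an early response gene, rose to 11.5 FPKM from 5.11 ± 0.143, with the same 3 calls adjusted over the list alone.

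Lists of pluripotency and of the germ layers were not called as sets after LIF withdrawal. Of 17 naive pluripotency genes limma called 0, with 8 at unadjusted p under 0.05 and 1 fall adjusted over the list alone. Zfp42 (Rex1) was at 190.5 ± 11.3 and 195 FPKM, and the list's median of 0.04 differed in sign from its mean of -0.01 and from the test (adjusted p = 0.691). Of 14 general pluripotency genes 0 were called, with 5 at unadjusted p under 0.05 (adjusted p = 0.637). Otx2, a homeobox gene of the formative epiblast, rose from 9.12 ± 0.149 to 25.7 FPKM, the 1 member of its list of 15 that was called (adjusted p = 0.234). Among 7 streak and mesendoderm genes Eomes rose to 3.72 FPKM and the WNT target Sp5 fell to 0.946 FPKM (adjusted p = 0.898). Sp5 was also the only call among 10 WNT targets (adjusted p = 0.158), Id2 among 13 BMP and NODAL targets (adjusted p = 0.696) and Ier3 among 15 FGF-ERK response genes (adjusted p = 0.376), where 2 rose adjusted over the list alone. Of 10 mesoderm, 7 blood and endothelium, and 11 extraembryonic endoderm genes limma called 0 each, with 8, 5 and 5 at unadjusted p under 0.05 (adjusted p = 0.516, 0.516 and 0.933). Map2 fell, as the only call of 7 neuroectoderm genes (adjusted p = 0.0965, but called lower at 0.0254 over 19 members without a filter), and Hoxd8 rose to 2.12 FPKM, as the only call of 5 Hox genes (adjusted p = 0.0965, but called higher at 0.0495 among genes of at least 1000 nt without opposite-strand exon overlap). Eomes was the call among 7 trophoblast genes, whose median of -0.05 and test (adjusted p = 0.784) differed in sign from the mean of 0.41. Only 4 cardiac genes passed the filter, too few for a set test, and Nppa rose to 1.17 FPKM from 0 in both ES libraries. Otx2, Eomes, Hoxd8, Nppa and Map2 lie outside the strand-clear set, so their changes could not be checked there and are uncertain. No member of the 2-cell-like list reached the filter.

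**Figure D2:**
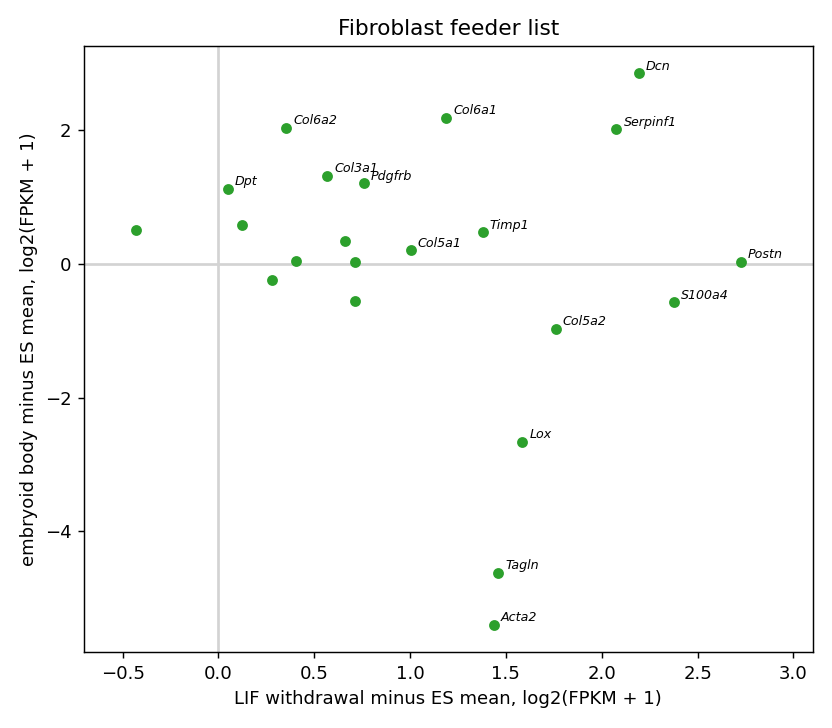
Fibroblast feeder list, with 1 point per gene: log2(FPKM + 1) change from the ES mean after LIF withdrawal (horizontal) and in the library labelled embryoid body (vertical). Genes at least 1 from 0 on either axis are named, and Acta2 lay at 1.44 and -5.40.

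The second comparison set the library labelled embryoid body against ES cells. Mmp3, a matrix metalloproteinase gene, was 87.4 FPKM in it and 0.369 ± 0.0711 FPKM (SD, n = 2) in ES cells. Its log2 change was 6.01 (SE 0.09 from the fit over all genes, limma adjusted p = 0.0071 in the strand-clear set). Lefty1 and Lefty2, inhibitors of NODAL signalling, rose in that set to 62.1 and 68.7 FPKM from 12.5 ± 0.298 and 9.25 ± 0.646, with log2 changes of 2.23 and 2.77. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 109 ± 2.44 to 729.8 FPKM (2.73, adjusted p = 0.0122). Acta2, the smooth muscle actin gene, fell from 85.7 ± 4.20 to 1.06 FPKM (-5.40, adjusted p = 0.0071). Over all genes none of these 5 was called, with limma adjusted p from 0.0788 for Acta2 to 0.137 for Lefty2.

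The size rule and the strand-clear fit named the same 8 largest rises. Besides Mmp3, Lefty2 and Spp1 they were Mmp10 at 21.7 FPKM, Mmp9 at 15.8, the peptide hormone gene Cck at 17.2, Igfbp5 at 15.6 and Dcn at 11.1, from 0.483 ± 0.125, 0.302 ± 0.0415, 0.445 ± 0.0948, 0.656 ± 0.0579 and 0.679 ± 0.0224 FPKM in ES cells. Among the largest falls, the myosin light chain gene Myl9 fell from 10.4 ± 0.547 to 0.925 FPKM and the annexin gene Anxa3 from 19.9 ± 1.23 to 2.60 FPKM in the strand-clear set. Itga3, an integrin subunit gene, fell to 3.84 FPKM there, Ahnak to 10.5 and Dlk1 to 1.18. By size alone, the actin-binding Tagln was at 1.26 FPKM against 54.5 ± 2.93, the collagen cross-linking enzyme gene Lox at 1.2 against 12.9 ± 0.0629, the protease gene Prss23 at 0.852 against 12.01 ± 0.120 and thrombospondin 1 (Thbs1) at 11.9 against 70.4 ± 3.01. In mm10, Mmp3 (ENSMUSG00000043613.7) lies on chromosome 9, 7445822 to 7455975, plus strand, Acta2 (ENSMUSG00000035783.8) on chromosome 19, 34241090 to 34255590, minus strand, and Lefty2 (ENSMUSG00000066652.5) on chromosome 1, 180893108 to 180899103, plus strand.

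Over all 15676 genes limma called 62 genes, each of them higher. Of these, 60 were listed at 0 in both ES libraries, so their p-values measure no spread of their own. None met the naming rule, so the size rule took its place, as the rule provides. In the strand-clear set limma called 165 genes, 108 higher and 57 lower, against a mean of 0.58 in simulated unchanged libraries. The set held 3 of the 62, all called in both fits. By size, 371 genes were at least 2-fold from both ES libraries (256 higher), and 147 against 3.44 in simulated unchanged libraries in the strand-clear set. Over all genes the simulation gave 379, with ES-pair differences drawn with random signs among genes of like level. This library lay nearer ES 1 in 92.1% of the pseudogenes that separated the ES libraries, so 379 is no matched background for the 371. The number of calls ranged from 0 to 165 over the gene sets tried, so the strand-clear calls rest on a set chosen after seeing the data.

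Among the lists, naive pluripotency genes were higher as a set in the library labelled embryoid body (median 0.46, camera adjusted p = 0.000624, and adjusted p = 0.881 with an estimated correlation). Of 17 members limma called 0 over all genes, with 13 at unadjusted p under 0.05 and 2 rises adjusted over the list alone. Tcl1, a coactivator of AKT, rose in the strand-clear set from 3.89 ± 0.464 to 14.9 FPKM (adjusted p = 0.0237), and Zfp42 was at 233 FPKM. Imprinted genes were lower as a set (median -0.57, adjusted p = 0.000624, and adjusted p = 0.881 with an estimated correlation), with 0 of 22 called, 13 at unadjusted p under 0.05 and 5 falls adjusted over the list alone. Rian fell to 314 FPKM, Dlk1 to 1.18 and Peg10 from 126 ± 1.21 to 57.1 in the strand-clear set. The mitochondrially encoded list was higher (median 0.84, adjusted p = 0.00598, and adjusted p = 0.881 with an estimated correlation), with 0 of 12 called and 4 at unadjusted p under 0.05, and mt-Nd1 was at 1310.0 ± 100.9 and 2490.0 FPKM. Of its members 5 (mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8) were at least 2-fold apart between the ES libraries, and the median was 0.45 against ES 1 alone and 0.96 against ES 2 alone. That call was also lost without genes that overlap the opposite strand. Proliferation genes (median -0.14, adjusted p = 0.0196) and germline genes (median -0.40, adjusted p = 0.0392) were lower as sets, each at adjusted p = 0.881 with an estimated correlation. The proliferation call was lost under 5 other settings as well and the germline call under 2. Limma called 0 of their 20 and 7 members, with 9 and 4 at unadjusted p under 0.05, and Top2a, the topoisomerase of dividing cells, was at 396 ± 0.977 and 370.5 FPKM.

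Fibroblast feeder genes went both ways in the library labelled embryoid body. Of 22 members limma called 1, Dpt, which was listed at 0 in both ES libraries and at 1.19 FPKM, and adjusted over the list alone 7 rose and 3 fell (median 0.28, camera adjusted p = 0.158). In the strand-clear set Dcn, Serpinf1, Pdgfrb and the collagen genes Col3a1, Col6a1 and Col6a2 rose while Acta2 fell, and the list was called higher (adjusted p = 0.0474, a set chosen after seeing the data). Over all genes the list stood at adjusted p = 0.881 with an estimated correlation, which was not run in the strand-clear set. BMP and NODAL targets were not called (0 of 13, with 10 at unadjusted p under 0.05, adjusted p = 0.528), though 2 members, Lefty1 and Lefty2, rose adjusted over the list alone. LIF-STAT3 targets were not called either (0 of 16, with 10 at unadjusted p under 0.05, adjusted p = 0.28), and adjusted over the list alone 1 rose and 3 fell. Among strand-clear genes, Fos fell to 7.31 FPKM and Ier3 rose to 16.1, and Socs3 was at 38.4 FPKM. Of 15 formative and primed epiblast genes 0 were called over all genes, with 7 at unadjusted p under 0.05 and 3 rises adjusted over the list alone (adjusted p = 0.86). Zic2, a zinc finger gene of the epiblast, rose in the strand-clear set from 5.96 ± 0.559 to 18.3 FPKM. Among the other lineage lists limma called 0 members. The camera adjusted p was 0.84 for streak and mesendoderm, 0.435 for mesoderm, 0.78 for blood and endothelium, 0.691 for extraembryonic endoderm, 0.427 for neuroectoderm, 0.28 for trophoblast and 0.615 for Hox genes. The numbers at unadjusted p under 0.05 were 4, 6, 3, 7, 6, 4 and 2 in that order. Adjusted over the list alone, 1 streak gene fell, and 1 neuroectoderm and 1 trophoblast gene rose while 1 of each fell. Within the strand-clear genes, Sp5 of the streak list and Nes (nestin) of the neuroectoderm list fell, to 0.673 and 2.11 FPKM. Streak and mesendoderm genes had a median of 0.17 and a mean of -0.04. FGF-ERK response genes (adjusted p = 0.516), WNT targets (adjusted p = 0.0965) and general pluripotency genes (adjusted p = 0.784) were not called as sets either, with 0 members called by limma and 7 at unadjusted p under 0.05 in each. Adjusted over the list alone, 1 member of each fell and 1 FGF-ERK response gene rose.

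The library labelled embryoid body and the LIF-withdrawal library were compared by size, since each is a single library, and a limma contrast whose spread comes from the ES pair alone was kept as an alternative. Acta2, Myl9 and Ankrd1 lay lower in the library labelled embryoid body, where Acta2 was at 1.06 FPKM against 234, Myl9 at 0.925 against 23.4 and the muscle ankyrin repeat gene Ankrd1 at 0.0682 against 9.64. Mmp3 was higher in it, at 87.4 against 9.50 FPKM, as were Ifitm1 at 294 against 42.1, Lefty1 at 62.1 against 8.34 and the transcription factor gene Tfap2c at 11.1 against 0.836. Over all genes the rule also named Vaultrc5 and Tpi-rs11 as highest and CT010467.1, Slc24a5 and Cd247 as lowest. Vaultrc5, a vault RNA gene, was at 46.7 FPKM in ES 1 and 0 in ES 2, so it separated the ES libraries as well. Altogether 746 genes were at least 2-fold higher and 1590 at least 2-fold lower in the library labelled embryoid body, and 103 and 237 in the strand-clear set. Against 10000 random lists matched on size and expression, the median difference of the naive list (0.52) was at percentile 100 and that of the feeder list (-0.44) at percentile 0.

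Some genes changed in both comparisons with ES cells. For strand-clear genes, 27 genes were called higher in both, among them Mmp3, Mmp9, Mmp10, Igfbp5, Dcn and Cck, and 11 lower in both, among them Fos, Kis2, Dlk1 and Rian. Independent lists of the same sizes would share 2.63 and 0.357 genes, and simulated unchanged groups against the same ES libraries shared 0. Those groups had a mean of 0.58 limma calls, so they could hardly share any, and the 0 is no background for these overlaps. Another 8 genes were higher after LIF withdrawal and lower in the library labelled embryoid body (1.39 for independent lists), including Acta2, Myl9 and Ankrd1, and 2 went the other way (0.677), Ifitm1 and Tfap2c. The log2 changes had a covariance of 0.0475, against 0.00658 in simulation, and r = 0.275 against 0.332. With a different ES library as the control of each comparison, the covariance in this set was 0.0372 or 0.0448 and r was 0.203 or 0.255. Over all genes 1 gene was called higher in both, with 4.54 for independent lists. The covariance over all genes was 0.0199 against 0.0835 in simulation, r was 0.0408 against 0.333, and with a different ES library for each the covariance was -0.211 or 0.05 and r -0.288 or 0.109. In the strand-clear set the covariance with separate ES libraries (0.0372 or 0.0448) stayed above the simulated 0.00658. This argues against noise of the shared ES libraries as its whole source in that set, unless the ES libraries came from a common culture. The ES pair could not be split with 2 libraries kept on each side, so the calls were not repeated that way. Part of the overlap of calls may therefore come from the shared controls.

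The series was registered as non-coding RNA profiling, and the last comparison was of long non-coding with protein-coding genes. After LIF withdrawal, Gm37376, Gm26825 and Gm11583 had the largest rises among long non-coding genes, each from 0 in both ES libraries, to 406, 324 and 266 FPKM. Their exons are covered by opposite-strand exons over 100%, 91.8% and 100% of their length, Gm37376 by the abundant nuclear RNA Malat1 (2526 FPKM in ES cells) and Gm11583 by the importin gene Kpnb1 (366 FPKM). Xist, the X-inactivation transcript, went from 1.38 ± 0.133 to 14.4 FPKM and overlaps genes on the opposite strand, so its level is uncertain. When tested in the strand-clear set, Gm26767, 4833413E03Rik and 4933409D19Rik rose to 6.16, 5.34 and 5.19 FPKM from 0 in both ES libraries, and Kis2, Rian and Gm37352 fell.

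Over all genes limma called 538 of 1672 long non-coding genes higher after LIF withdrawal (32.2%) against 342 of 12359 protein-coding genes (2.77%), an odds ratio of 16.7 (95% confidence interval 14.3 to 19.4, two-sided Fisher's exact test, p = 5.62e-295, across genes that are not independent replicates). These calls include genes listed at 0 in both ES libraries. By the size rule, which uses no p-value, the odds ratio was 13.8. The share at least 2-fold higher was 73.1% where exons overlapped those of an opposite-strand gene of 10 FPKM or more, and 4.85% of 783 long non-coding genes outside all opposite-strand gene bodies. Protein-coding genes showed 11.9% and 2.33% in the same positions. In the library labelled embryoid body the share for long non-coding genes was 0.464% with such overlap and 1.53% outside. Among strand-clear genes, 24 of 590 long non-coding genes (4.07%) and 151 of 6585 coding genes (2.29%) were called higher after LIF withdrawal, an odds ratio of 1.81 (95% confidence interval 1.11 to 2.82, Fisher's exact p = 0.0116), and in the library labelled embryoid body the odds ratio for genes called higher was 1.14 (p = 0.723), against 8.65 over all genes (7 of 1672 and 6 of 12359, p = 0.000301). For genes called lower after LIF withdrawal the counts were 8 of 590 (1.36%) against 37 of 6585 (0.562%), an odds ratio of 2.43 (95% confidence interval 0.974 to 5.34, Fisher's exact p = 0.0284). Over all genes that odds ratio was 2.25 (Fisher's exact p = 0.0312), but without a filter it was 1.00 (p = 1) and without opposite-strand overlap 1.58 (p = 0.637), so a lower direction was not settled. Of the 29 named long non-coding genes tested after LIF withdrawal, Xist rose and Lncenc1, a transcript of naive ES cells, fell to 14.6 from 33.9 ± 0.295 FPKM (camera adjusted p = 0.123). Of 22 Platr genes, ES-cell transcripts with pluripotency-associated expression, Platr23 rose and Kis2 and Lncenc1 fell (adjusted p = 0.419). In the library labelled embryoid body 0 of either list were called by limma, with 9 and 7 at unadjusted p under 0.05 (adjusted p = 0.784 and 0.84), and Malat1 was at 2526 ± 93.8 FPKM in ES cells and 4853 in it. Within the strand-clear genes, Gm43062, Gm15892 and Gm43279 rose in the library labelled embryoid body, to 11.7, 14.4 and 14.9 FPKM, and Kis2, Gm37352 and Gm26945 fell.

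**Figure D3:**
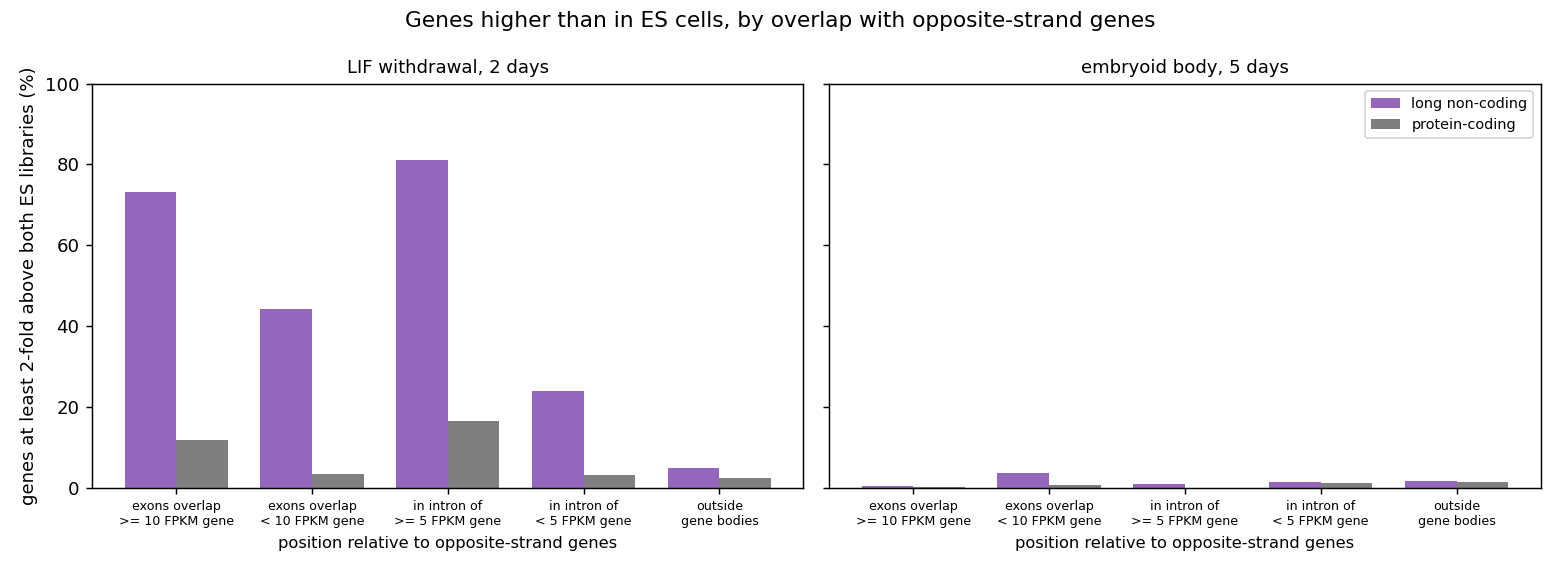
Percentage of long non-coding (purple) and protein-coding (grey) genes at least 2-fold above both ES libraries after LIF withdrawal (left) and in the library labelled embryoid body (right), by position relative to genes on the opposite strand. After LIF withdrawal 73.1% of long non-coding genes with exons opposite a gene of 10 FPKM or more were higher, against 4.85% of those outside opposite-strand gene bodies.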

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

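The tests of the feeder list were chosen after the result was seen, and they count members at least 2-fold from both ES libraries in place of called members. Acta2, at 85.7 ± 4.20 FPKM (SD, n = 2) in ES cells, was higher after LIF withdrawal (234) and lower in the library labelled embryoid body (1.06), a log2 difference of -6.83 between the derived libraries. Others above both ES libraries after LIF withdrawal and below both in the library labelled embryoid body were Tagln (log2 difference -6.08), Thbs1 (-4.27), Lox (-4.24), Prss23 (-4.00), Myl9 (-3.67) and Ankrd1 (-3.32). The opposite order was seen for Tfap2c (2.72), a trophoblast and germ cell transcription factor gene, and Ifitm1 (2.77). They stand out by direction alone, because the derived libraries lay on opposite sides of both ES libraries. The difference was not tested with replicates of either derived library, and the limma contrast between them, whose spread comes from the ES pair alone, was used only to count genes.

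Contractile genes such as Acta2 and Tagln are abundant in fibroblasts, and the ES cultures held fibroblast feeders, so a different share of feeder cells was weighed. For the library labelled embryoid body the test argues against it as the whole cause: of 10 feeder-list genes at least 2-fold from both ES libraries 70.0% went up, with Dcn at 11.1 FPKM and Acta2 at 1.06, and a change in share alone would move them one way. Limma calls in the strand-clear set were 6 up and 1 down, which the rule, set for called members, would have counted as one way. The reading thus depends on which members are counted. After LIF withdrawal 100% of the 10 such genes went up, so a larger share of feeders stays open there and may account for part of the rise of Postn, Dcn and Acta2. The 100% covers only members at least 2-fold apart, and the changes were uneven. Over the 22 members tested the median log2 change was 0.88, with Postn and Dcn well above it. A change in the state of the feeder cells, and a response of the ES-derived cells to LIF withdrawal, were not tested and stay open.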

How the results depend on the processing

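The restrictions by strand overlap and length were chosen after seeing the data; the other settings were fixed before. No result that was called reversed, while the covariance of both comparisons over all genes turned from 0.0199 to -0.211 with a different ES library for each. Several uncalled lists changed direction. The feeder list of the library labelled embryoid body turned lower at a mean of at least 5 FPKM (camera adjusted p = 0.9). Naive pluripotency genes turned higher after LIF withdrawal with quantile normalization. Epithelial genes turned lower in the library labelled embryoid body without a filter. Of the list tests 530 stayed on their side of the threshold whatever their direction, 21 lost a call and 9 gained one. Of the changes of single named genes, 1996 kept their call or, where uncalled, stayed uncalled within the ES pair's SD. Another 162 moved by more than that SD without a call, 157 gained a call and 47 lost it. With an ES library left out, a change stays within that SD by construction. The cause was not tested except where fewer genes were tested by construction. The estimated correlation could hardly call any list, because its test has 1 degree of freedom. Depth limits genes near the floor of 0.095 to 0.166 FPKM.

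For LIF withdrawal against ES cells (1203 calls), limma called 140 genes at a mean of at least 5 FPKM, 487 without opposite-strand exon overlap, 360 with that and a length of at least 1000 nt, and 220 outside opposite-strand gene bodies. Quantile normalization gave 1192 calls with 918 higher and 274 lower, against 1147 and 56. For the library labelled embryoid body (62 calls) limma called 131 with a pseudocount of 0.1, 138 without a filter, 26 at a mean of at least 5 FPKM, 165 outside opposite-strand gene bodies, and 0 without overlap, with long genes alone or without a variance trend, beside 4338 genes at unadjusted p under 0.05 as reported. Quantile normalization gave 49 calls, 36 higher and 13 lower.

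By size, LIF withdrawal (1517 genes) gave 283 at a mean of at least 5 FPKM, 786 without overlap, 858 with long genes alone, 347 with both and 198 outside gene bodies, and 1743 to 2240 with either ES library left out. The library labelled embryoid body (371) gave 1012 with a pseudocount of 0.1, 157 at a mean of at least 5 FPKM, 234 with long genes alone, 180 with both restrictions and 147 outside gene bodies, and 525 to 1068 with either ES library left out (1068 without ES 1). Between the derived libraries (2336) the limma contrast called 1236, and the size rule gave 583, 1539, 1075, 527 and 340 under the filter and the same restrictions in that order; quantile normalization gave 1097 higher and 1217 lower, against 746 and 1590. Between the ES libraries (684) it gave 1112 with a pseudocount of 0.1, 232 at a mean of at least 5 FPKM, 25 with long genes alone, 20 with both and 15 outside gene bodies.

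The called lists numbered 5 without a filter, which added neuroectoderm (adjusted p = 0.0254) and proliferation (0.0236), both lower, and 0 with an estimated correlation after LIF withdrawal (3 as reported), and 2 without overlap, 3 outside gene bodies and 0 with an estimated correlation in the library labelled embryoid body (5 as reported, and 5 without a filter with histones, lower at 0.0196, in place of germline genes). Other lists gained a call after LIF withdrawal, Hox genes (higher, 0.0495 with both restrictions) and proliferation (lower, 0.0479 with median-of-ratios scaling), or in the library labelled embryoid body, feeder genes (higher, 0.033 with both restrictions and 0.0474 outside gene bodies), histones (lower, 0.0479 with median-of-ratios scaling) and small structural RNAs (higher, 0.0356 at a mean of at least 5 FPKM). Genes called in both comparisons (1) numbered 68 with a pseudocount of 0.1, 27 without a filter, 5 at a mean of at least 5 FPKM, 2 with median-of-ratios scaling, 8 with quantile normalization, 0 without overlap or with long genes alone, 15 with both and 38 outside gene bodies. The odds ratio for long non-coding genes (16.67) was 5.82 without a filter, 32.58 at a mean of at least 5 FPKM, 10.36 without overlap, 5.34 with both and 1.81 outside gene bodies. No paired analysis was possible because the derived groups hold a single library each and share fewer than 2 replicate numbers with ES cells.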

Other observations

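The gene families were chosen, and the test of depth on pseudogenes and the deciding value for induction outside gene bodies were set, only after the result was seen. In the strand-clear set, limma called the matrix metalloproteinase genes Mmp3, Mmp9, Mmp10 and Mmp13 higher in both derived libraries, 4 of the 8 tested. The chemokine genes Ccl20, Cxcl1 and Cxcl5 were called higher after LIF withdrawal, 3 of 5. In the library labelled embryoid body 0 of these 5 were called higher and Cxcl12 was called lower, with a median log2 change of -0.174. Fos and Fosb of 3 AP-1 subunit genes were called lower in both libraries. Of 13 collagen genes Col3a1, Col6a1, Col6a2 and Col6a3 were called higher in the library labelled embryoid body and Col8a1 lower, with a median log2 change of 0.08. These families were picked because members stood among the largest changes, so the counts describe these genes and are no test of the family. Feeder genes rose with them after LIF withdrawal (8 of 22, median log2 change 0.88). A larger share of feeder cells thus stays open as part of the rise of the metalloproteinase and chemokine genes. Mmp3 and Mmp10 rose by far more than that median.

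Other lists were not called as sets after LIF withdrawal. Glycolysis genes (0 of 16 called by limma, 7 at unadjusted p under 0.05, adjusted p = 0.16), epithelial genes (0 of 17, 8, 0.28), DNA methylation genes (0 of 12, 5, 0.812), Polycomb genes (0 of 22, 9, 0.637) and proliferation genes (0 of 20, 6, 0.0635) were not called. Mitochondrially encoded genes (0 of 12, 2, 0.982), germline genes (0 of 7, 4, 0.982), replication-dependent histones (0 of 20, 7, 0.933) and small structural RNAs (0 of 13, 1, 0.0821) were not called either. Small structural RNAs had a median log2 change of -1.03 and a mean of -1.54, and 7 of them were at least 2-fold apart between the ES libraries. Their median was -1.59 against ES 1 alone and -0.098 against ES 2 alone. In the library labelled embryoid body these medians were 0.306 and 1.31. Germline genes and histones had medians of 0.21 and 0.17 with the test in the other direction, and Polycomb genes a median of -0.02 and a mean of 0.01. In the library labelled embryoid body the adjusted p was 0.158 for glycolysis, 0.784 for epithelial genes, 0.158 for DNA methylation, 0.516 for Polycomb, 0.0635 for histones and 0.134 for small structural RNAs (called higher at 0.0356 with a mean of at least 5 FPKM), with 0 calls by limma and 4, 6, 6, 10, 9 and 0 members at unadjusted p under 0.05. Against random lists, the difference between the derived libraries was at percentile 100 for glycolysis (0.34), mitochondrially encoded (1.09) and small structural genes (1.79), and at percentile 0 for histones (-0.70).

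Long non-coding genes higher in the LIF-withdrawal library form the pattern most in need of follow-up, and reads of the opposite strand counted in that library are a candidate explanation. The share at least 2-fold higher was 4.64 times as high where exons overlap an expressed opposite-strand gene as where no exon overlaps, it was 16.7 times as high inside the introns of such genes as outside gene bodies, and among 177 low genes at least 90% covered the level followed that of the partner gene (Spearman rho 0.684 across genes, 0.00281 in the library labelled embryoid body). Over the 69 of these whose partner was at 10 FPKM or more the median was 16.9% of the partner; in the library labelled embryoid body it was 0 over 65. Genomic DNA is argued against as the whole cause. Of 6070 genes without opposite-strand exon overlap that were at 0 elsewhere, 12.4% were above 0, and the level of covered genes followed the partner gene. The share above 0 was lower in the other libraries (2.64%, 2.15% and 8.6% in ES 1, ES 2 and the library labelled embryoid body), so a small contribution stays open. The 6070 include genes inside opposite-strand introns, so the share does not separate genomic DNA from opposite-strand reads. Induction by LIF withdrawal cannot be told apart from a remainder of this source: the planned test, without exon overlap, gave an odds ratio of 6.5 but left introns in, and outside gene bodies it was 2.14 (95% confidence interval 1.45 to 3.09).

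Pseudogenes and short genes set ES 1 and the library labelled embryoid body apart from ES 2 and LIF withdrawal. Reads shared with near-identical copies may account for it, since processed pseudogenes were at least 2-fold apart between the ES libraries 4.09 times as often as coding genes matched on length and level (40.7% against 9.96%). Coding genes under 600 nt were apart 141.0 times as often as those of 2000 nt or more (21.0% against 0.149%), but the excess over matched genes argues against short models as the whole cause, a reading set after the values were seen. Library depth is argued against, since in 92.1% of these pseudogenes the library labelled embryoid body lay nearer ES 1. Its estimated depth equals that of ES 2, to within bins of 0.05 on the log2 scale. No biological explanation was tested.

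Olfr986 and Zfp202 lie next to each other on the plus strand of chromosome 9, at 40180920 to 40190134 and 40192316 to 40213604, and both rose after LIF withdrawal while Olfr986 was listed at 0 in the other 3 libraries. This neighbour pair was picked after its values were seen, and no test was made of a shared transcript.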
